A study of Mus musculus with 20 samples.

How the data were processed

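The series holds 20 arrays of total RNA from the mouse hypothalamic cell lines mHypoE-46 (E46) and mHypoA-2/12 (A2/12), in 5 groups of 4: E46 controls, E46 with serotonin labelled 100 and labelled 1 (µg/ml), A2/12 controls and A2/12 with serotonin labelled 100. Per the submitters' processing notes, the authors made the deposited log2 values from the scanned Affymetrix gene arrays with RMA. The version is not given in the sources used here. RMA corrects for background, normalizes between arrays and summarises the probes of a probe set. The table has 35556 probe sets. No detection calls were used, so folds of genes near the background are compressed toward 0.

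Gene names came from the array's annotation in a reference table matched by Entrez ID (21185 probe sets), and no coordinates were used. Of the probe sets, 21218 have 1 symbol, 1881 have several and 12457 have none. The latter 2 kinds were left out of the gene tests. Of 1386 genes with several probe sets the one with the highest mean over all arrays was used, which left 18820 genes. A background level was taken as the 95th percentile of 1157 odorant and pheromone receptor genes, and ranged from 4.35 to 4.66 over the groups. Between 11816 and 12834 of the other 17663 genes lay above it.

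Groups and doses follow the titles and source names. In the E46 serotonin arrays the description gives the doses the other way round, which was run as an alternative. The labels do not say whether the 4 arrays of a group came from separate cultures.

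A linear model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (15 residual degrees of freedom), with moderated t-tests by eBayes and Benjamini-Hochberg adjusted p-values. A gene was called at an adjusted p below 0.05. The comparisons were E46 at the labelled 100 and at the labelled 1 against controls, the labelled 100 against the labelled 1, A2/12 at the labelled 100 against controls, the difference of both responses at 100, and E46 against A2/12 controls. The number of arrays limits the precision: the median standard error of a change was 0.100, with a 95% confidence interval of ± 0.209 (0.142 and ± 0.296 for the difference of responses). In all, 33 gene lists with 734 measured genes of 805 were tested with camera, at a preset correlation of 0.01 and, as an alternative, with the estimated correlation. For each list the members passing over all genes and over the list alone were counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

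The genes named are Npy, the 10 largest increases and decreases among called genes whose groups did not overlap (for the difference of responses, among called genes), up to 4 members of each described list with the smallest adjusted p, and the serotonin receptor, transport and breakdown genes as levels. Where fewer than 10 genes passed, the 5 smallest p-values are named. Predicted genes, olfactory and vomeronasal receptors, small RNAs and ribosomal pseudogenes were left out of the largest changes. Any gene named outside this rule is said to be chosen after its values were seen.

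The code was tested on simulated data with known changes. It recovered 90.9 to 100% of 2-fold, 43.3 to 92.5% of 1.5-fold and 0 to 19.4% of 1.2-fold changes, and 4.08 to 8.07% of its calls were false. The shifted list was called in each comparison, with 0 of 32 unshifted lists called by camera. The simulated genes varied independently of each other. The 0 of 32 therefore does not tell how often a list of correlated genes is called without a shift. The mitosis list, for example, had an estimated correlation of 0.479. Alternatives were a fit per cell line, trended and robust eBayes, array weights, the replicate number or the position number as a block, each position number alone, quantile normalization, median centring, filters on dim genes, other ways of choosing probe sets, a fold threshold of 1.5, the other dose label and leaving out each array in turn. Others, chosen after seeing the data, left out 4 arrays with an upper quartile under 8.2, used the upper quartile as a covariate, or left out 2 control arrays, E46 replicate 3 and A2/12 replicate 4, with high values of some intestinal or macrophage genes. An array was taken to stand apart in its group of 4 by Dixon's test at 95%.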

Results

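Gene expression was measured on 20 microarrays of total RNA from 2 mouse hypothalamic neuronal cell lines, mHypoE-46 (Hypo-E46 in the titles) and mHypoA-2/12 (Hypo-A2/12), called E46 and A2/12 below. The labels call E46 sensitive to serotonin and A2/12 unresponsive, and the stated aim was to follow the mRNA of the appetite peptide Npy. Cells were kept in medium without serum and then left as controls or given serotonin, with a 24 h exposure. There were 5 groups of 4 arrays: E46 controls, E46 at serotonin labelled 100 µg/ml, E46 at serotonin labelled 1 µg/ml, A2/12 controls and A2/12 at serotonin labelled 100 µg/ml. For the E46 serotonin arrays a second label gives the doses crossed, with 1 for the arrays titled 100 and 100 for those titled 1. The doses below are therefore those of the titles, written as labelled 100 and labelled 1. Values are log2 expression levels, and 18820 genes were tested. The correlation between any 2 arrays lay between 0.927 and 0.995. A level under about 4.38 in E46 controls and 4.36 in A2/12 controls was within the range of 1157 odorant and pheromone receptor genes, of which 95% lay lower. Group values are means ± SD over 4 arrays, changes are log2 differences ± SE with 4 arrays in each group, and a change was called at an adjusted p below 0.05. The p-values measure only the spread between arrays, since no label says which arrays came from separate cultures, and the number of arrays limits the precision.

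The first comparison asked what serotonin labelled 100 did in E46, the line described as sensitive. Genes of the amino acid and integrated stress response rose, while genes of cholesterol synthesis fell. Extracellular matrix genes fell too, but their list was not called with an estimated correlation (adjusted p = 0.0705 with an estimated correlation). Car6, which encodes a secreted carbonic anhydrase, had the largest increase, from 5.40 ± 0.07 to 9.81 ± 0.14, a change of 4.41 ± 0.10. Fmod, which encodes the collagen-binding proteoglycan fibromodulin, had the largest decrease, from 10.44 ± 0.07 to 6.34 ± 0.84, a change of -4.10 ± 0.25. Npy lay at 4.45 ± 0.11 in controls and 4.55 ± 0.08 with serotonin, near the level of the receptor genes, and its change of 0.10 ± 0.12 was not called (adjusted p = 0.577). So close to the background a change of Npy, above all a decrease, may not be seen, here or in the comparisons below.

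Of the 18820 genes, 7451 changed: 3826 rose and 3625 fell, 435 and 773 of them by at least 2-fold. The other large increases were Avil (3.32 ± 0.14), which encodes the actin-binding protein advillin, Fam110c (3.24 ± 0.12), the stress transcription factor Atf3 (3.23 ± 0.11), the cystine importer Slc7a11 (3.17 ± 0.14), the chemokine Cxcl10 (3.02 ± 0.19), the cysteine-making enzyme Cth (3.00 ± 0.14), the secreted glycoprotein Stc2 (2.97 ± 0.09), the efflux transporter Abcc4 (2.94 ± 0.11) and Ppp1r15a (2.88 ± 0.09), a phosphatase subunit that restores translation after stress. Among the other large decreases were 4 small leucine-rich proteoglycans of the matrix: Omd (-3.44 ± 0.20), Ogn (-3.43 ± 0.38), Prelp (-3.42 ± 0.33) and Aspn (-3.38 ± 0.39). They also held Islr (-3.64 ± 0.23), Nrep (-3.59 ± 0.38), the opioid peptide precursor Penk (-3.53 ± 0.28), the growth factor Igf1 (-3.48 ± 0.23) and the galectin Lgals2 (-3.42 ± 0.21).

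Gene lists fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives not marked as added later, were compared with all other genes by camera. The list with the strongest shift was the ATF4 and amino acid response, the transcription programme of the integrated stress response: 28 of 29 measured members rose, also 28 when adjusted over the list alone, with a mean change of 1.46 (camera adjusted p = 9.18e-25, adjusted p = 0.0235 with an estimated correlation). Besides Atf3, Slc7a11 and Stc2 it holds Trib3, a pseudokinase induced by amino acid shortage (2.62 ± 0.11). Of 27 antioxidant genes controlled by NRF2, 18 rose and 4 fell (19 and 6 adjusted over the list alone; camera adjusted p = 5.80e-06, adjusted p = 0.0705 with an estimated correlation). Among them were the heme-degrading enzyme Hmox1 (2.00 ± 0.07) and Gclc (1.90 ± 0.08) and Gclm (1.51 ± 0.07), the subunits of the first enzyme of glutathione synthesis. Of 30 interferon-stimulated genes 16 rose and 6 fell (17 and 6 adjusted over the list alone; camera adjusted p = 0.00424, adjusted p = 0.429 with an estimated correlation). Ifit1 was at 1.94 ± 0.12 and Usp18 at 1.56 ± 0.14. Of 28 NF-kB and inflammatory genes 14 rose and 3 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.00432, adjusted p = 0.330 with an estimated correlation). Those that rose include the prostaglandin synthase Ptgs2 (1.96 ± 0.07) and the chemokine Ccl5 (2.83 ± 0.11). Among 4 metallothionein and zinc export genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0342, adjusted p = 0.125 with an estimated correlation), the zinc exporter Slc30a1 most (1.62 ± 0.15). With the correlation between genes estimated from the data instead of preset, the ATF4 list was still called. The other 4 rising lists were not.

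Among the lists that shifted down, 20 of 21 cholesterol synthesis and uptake genes fell (20 fell and 1 rose adjusted over the list alone; median change -1.06; camera adjusted p = 9.04e-16, adjusted p = 0.0235 with an estimated correlation). Examples are the sterol reductases Tm7sf2 (-2.09 ± 0.11) and Dhcr7 (-1.40 ± 0.07) and Hmgcs1 (-1.65 ± 0.10), an early enzyme of the pathway. Of 32 extracellular matrix and TGF-beta response genes 28 fell and 0 rose (28 adjusted over the list alone; mean -1.20; camera adjusted p = 2.33e-16, adjusted p = 0.0705 with an estimated correlation). The falling genes include the matrix glycoprotein Thbs1 (-2.73 ± 0.16), the matricellular Ccn2 (-2.03 ± 0.12), and the contractile genes Tagln (-1.98 ± 0.10) and Acta2 (-1.95 ± 0.13). Of 17 astrocyte and progenitor markers 12 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 4.39e-05, adjusted p = 0.0235 with an estimated correlation). The glial fatty acid binding protein Fabp7 was at -2.28 ± 0.15, the Notch target Hes1 at -1.37 ± 0.09 and the glutamate transporter Slc1a3 at -1.82 ± 0.13. The cholesterol and astrocyte lists were called with an estimated correlation as well, and the matrix list was not.

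Smaller downward shifts were called for 6 further lists. Of 26 mitosis genes 20 fell (21 adjusted over the list alone; camera adjusted p = 3.02e-06, adjusted p = 0.330 with an estimated correlation), such as the proliferation marker Mki67 (-1.01 ± 0.10) and the kinase Aurkb (-0.70 ± 0.05). Of 30 oxidative phosphorylation genes 14 fell (16 adjusted over the list alone; camera adjusted p = 0.000996, adjusted p = 0.330 with an estimated correlation), Ndufa4 among them (-0.79 ± 0.08). Among 19 fatty acid synthesis genes 9 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.00939, adjusted p = 0.333 with an estimated correlation), with the elongase Elovl6 at -1.63 ± 0.08. Of 25 DNA replication genes 12 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.0377, adjusted p = 0.523 with an estimated correlation): thymidine kinase Tk1 fell (-1.57 ± 0.08) and the origin licensing factor Cdt1 rose (0.65 ± 0.07). In the neuron marker list 7 of 22 fell (7 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.230 with an estimated correlation). The dendritic protein Map2 (-1.79 ± 0.10) and the surface protein Thy1 (-1.56 ± 0.11) were among them. Of 29 peptide processing and secretion genes 10 fell (10 adjusted over the list alone; camera adjusted p = 0.0473, adjusted p = 0.230 with an estimated correlation), including the amidating enzyme Pam (-0.90 ± 0.07) and carboxypeptidase Cpe (-0.58 ± 0.07). None of these 6 was called with an estimated correlation. The DNA replication and the peptide processing list also lost their calls without some single arrays.

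The lists closest to the study's question were not called as wholes in E46. In E46 controls 18 of 36 neuropeptides, 14 of 37 appetite receptors and 6 of 14 serotonin receptors lay above the receptor gene background. So did 13 of 22 genes of serotonin synthesis, transport and breakdown. Changes of the other members are compressed toward 0, which limits what these list tests can show. Of 36 appetite and other hypothalamic neuropeptides 3 fell (2 adjusted over the list alone; camera adjusted p = 0.293): Penk, the nesfatin precursor Nucb2 (-0.52 ± 0.09) and the neurotrophin Bdnf (-0.29 ± 0.09). Among 37 receptors for appetite peptides and hormones 3 rose and 4 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.547). The receptor Npy1r, through which Npy acts, fell by 1.58 ± 0.10, from 7.51 ± 0.18 to 5.93 ± 0.11, the insulin receptor Insr rose by 0.58 ± 0.11 and Igf1r fell by 0.60 ± 0.09. Of 14 serotonin receptors 3 fell (3 adjusted over the list alone; camera adjusted p = 0.295): Htr1d (-0.66 ± 0.11), Htr2a (-0.43 ± 0.11) and Htr5b (-0.30 ± 0.10). The call of Htr5b was lost without E46 control replicate 2 (-0.18, adjusted p = 0.118) and without replicate 4 at the labelled 100 (-0.26, adjusted p = 0.0801). Of 22 genes of serotonin synthesis, transport and breakdown 3 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.555): Gch1, which makes the cofactor of tryptophan hydroxylase, rose by 2.16 ± 0.16, and the amine-degrading Maoa by 0.61 ± 0.07.

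The arrays carry a position in their scan names, with the numbers 5, 7 and 9, and each number holds arrays of every group. The position also has a row letter, which follows the order of the groups. Controls of this line lie in rows A and B, the labelled 100 in B and C and the labelled 1 in C and D. In the other line, controls lie in E and F and serotonin arrays in F and G. The labelled 1 thus shares no row with its controls, and the lines share no row. The position number does not account for a drift from row to row. Within the arrays at 5, 7 and 9 alone, 3183, 3469 and 871 genes changed, with 2 or fewer arrays per group, and with the position number as a block 7279 changed. If the doses of the second label are used, this comparison becomes the next one, with 2 genes.

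**Figure D1:**
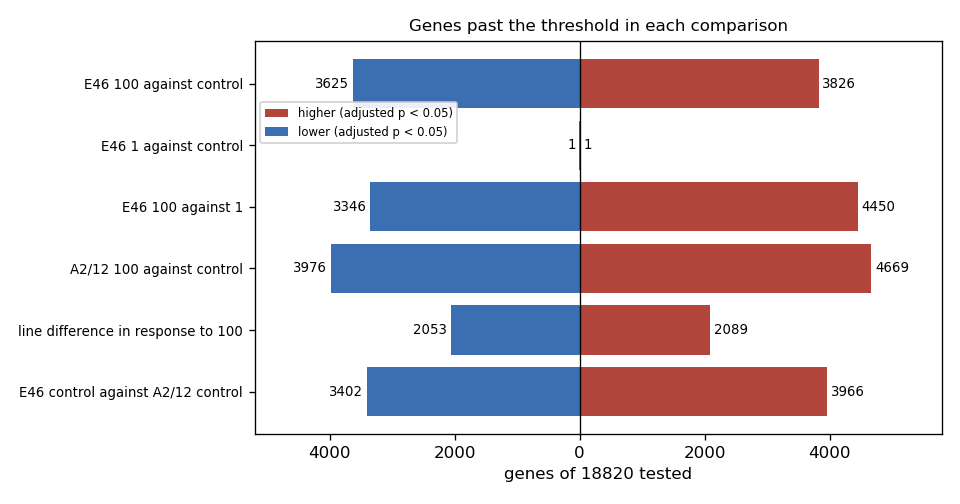
Number of genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left, of 18820 tested. E46 at serotonin labelled 1 differed from its controls in 2 genes, against 7451 at the labelled 100.

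The second comparison asked what the arrays labelled 1 showed in E46. Expression was close to that of the controls. The small nucleolar RNA Snord22 rose by 0.55 ± 0.07 (adjusted p = 0.0068), from 7.25 ± 0.13 to 7.79 ± 0.13, and Boc, which encodes a Hedgehog co-receptor, fell by 0.51 ± 0.08 (adjusted p = 0.0476), from 5.61 ± 0.12 to 5.10 ± 0.08. The call of Snord22 was lost with the cell line fitted alone (adjusted p = 0.278), within each position number, with a fold threshold of 1.5 and without the 4 arrays of low upper quartile (0.44, adjusted p = 0.278), an alternative chosen after seeing the data. The call of Boc was lost in the same alternatives, in others, and without any 1 of 6 of the 8 arrays. Npy was at 4.54 ± 0.36, a change of 0.10 ± 0.12 (adjusted p = 0.705). Car6 was at 5.58 ± 0.20 and Fmod at 10.25 ± 0.09.

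By limma 2993 genes had an unadjusted p below 0.05, where 941 are expected by chance, and 2 were called. The next smallest p-values belonged to Olfr959 (0.75 ± 0.13, adjusted p = 0.0571), Stx19 (0.49 ± 0.09, adjusted p = 0.172) and Pmel (-0.43 ± 0.08, adjusted p = 0.172), none of which was called. The 4 metallothionein and zinc export genes shifted up as a list (mean 0.27; camera adjusted p = 0.00284; adjusted p = 0.0394 with an estimated correlation), with 0 called over all genes and 3 adjusted over the list alone. The 27 insulin, leptin and energy sensing genes shifted down (mean -0.11; camera adjusted p = 0.0339), with 0 called over all genes and 1 adjusted over the list alone, and this shift was not called with an estimated correlation (adjusted p = 0.971 with an estimated correlation). Its call was also lost without some single arrays. Of the 33 lists the other 31 were not called.

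Within the arrays at positions 5, 7 and 9 limma called 0, 0 and 1 genes (453, 3656 and 286 at an unadjusted p below 0.05), and 1 with the position number as a block. Without E46 replicate 2 at the labelled 1 it called 284 genes, without replicate 4 it called 4, and without any 1 of the other 6 arrays it called 1.

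In simulated data with as many arrays, 92.5% of genes changed 1.5-fold in either direction and 98.5% of those changed 2-fold were recovered for this comparison. Of genes changed 1.2-fold, 4.48% were recovered. The simulation gave a gene the same spread in every group and independent noise in each array. The real arrays labelled 1 had a root mean square difference from the rest of their group of 0.221 to 0.292, against 0.149 to 0.210 at the labelled 100. Recovery in the real arrays may therefore be lower. Across genes, which are not independent replicates, the changes at the 2 doses had a Pearson correlation of 0.192 and a Spearman correlation of 0.227. Because both share the same controls, a correlation arises without any effect: in 100 simulated draws it averaged 0.50. The covariance of both changes, 0.0183, was above the simulated 0.00696, and with the controls divided between the doses the correlation was 0.120 and the covariance 0.0123 over 6 ways of dividing.

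Compared directly, the E46 arrays labelled 100 differed from those labelled 1 in 7796 genes, 4450 higher and 3346 lower, of which 537 and 653 by at least 2-fold. The genes with the largest differences were those of the comparison with controls: Car6 (4.23 ± 0.10), Avil (3.44 ± 0.14) and Fam110c (3.30 ± 0.12) were higher at the labelled 100, and Fmod (-3.92 ± 0.25), Islr (-3.56 ± 0.23) and Igf1 (-3.54 ± 0.23) were lower. The ATF4 list was higher in 28 of 29 genes (28 adjusted over the list alone; camera adjusted p = 1.38e-23). The cholesterol list was lower in 20 of 21 (20 adjusted over the list alone; camera adjusted p = 6.23e-16), and the astrocyte list was lower in 12 of 17 and higher in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 6.65e-05). These 3 lists were called with an estimated correlation too (adjusted p = 0.027 for each). The matrix list was lower in 27 of 32 genes (27 adjusted over the list alone; camera adjusted p = 1.61e-15; adjusted p = 0.089 with an estimated correlation) and the NRF2 list was higher in 17 and lower in 5 of 27 (18 and 6 adjusted over the list alone; camera adjusted p = 1.92e-05; adjusted p = 0.094 with an estimated correlation). The fatty acid, mitosis and oxidative phosphorylation lists (lower) and the interferon and NF-kB lists (higher) were also called with the preset correlation, with adjusted p from 0.375 to 0.519 with an estimated correlation. Npy was not called (0.00 ± 0.12, adjusted p = 0.981). Within positions 5, 7 and 9 the counts were 2051, 5107 and 1371, and 7710 with the position number as a block. With the doses of the second label every direction here turns.

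The third question was what serotonin labelled 100 did in A2/12, the line described as unresponsive. As in E46, Car6 rose most, from 5.17 ± 0.17 to 10.24 ± 0.15, a change of 5.07 ± 0.10, and the stress response genes Atf3 (3.00 ± 0.11), Cth (3.32 ± 0.14) and Trib3 (2.96 ± 0.11) rose. Inmt, which encodes a methyltransferase acting on tryptamine and related amines, fell most, from 11.77 ± 0.22 to 6.58 ± 1.51, a change of -5.19 ± 0.44. The angiotensin receptor gene Agtr2 fell from 9.89 ± 0.13 to 4.75 ± 0.77 (-5.14 ± 0.24). Npy was at 4.31 ± 0.08 in controls and 4.30 ± 0.06 with serotonin (-0.02 ± 0.12, adjusted p = 0.936).

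In this line 8645 genes changed, 4669 up and 3976 down, with 816 and 1212 changed at least 2-fold. Further large increases were Trem3, a myeloid-type receptor gene (3.59 ± 0.10), the class I-like gene H2-M1 (3.58 ± 0.15), the phosphatase Dusp9 (3.48 ± 0.15), the cytochrome oxidase subunit Cox6a2 (3.00 ± 0.11), the noncoding Snhg16 (2.99 ± 0.12) and Plcxd2 (2.96 ± 0.13). Further large decreases were Elobl (-5.08 ± 0.23), Medag (-4.88 ± 0.23), Aspn (-4.80 ± 0.39), Ranbp3l (-4.71 ± 0.33), the melanocortin receptor Mc5r (-4.58 ± 0.25), the aspartoacylase Aspa (-4.55 ± 0.27), Nrep (-4.55 ± 0.38) and the calcium sensor Vsnl1 (-4.48 ± 0.22).

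The ATF4 list rose in 27 of 29 genes (27 adjusted over the list alone; mean 1.28; camera adjusted p = 5.46e-16, adjusted p = 0.199 with an estimated correlation), with Chac1, a glutathione-degrading enzyme, at 2.40 ± 0.08. Mitosis genes fell in 25 of 26 cases (25 adjusted over the list alone; mean -1.06; camera adjusted p = 1.28e-14, adjusted p = 0.200 with an estimated correlation). Examples are cyclin B2 (Ccnb2, -2.27 ± 0.07), the centromeric histone Cenpa (-1.56 ± 0.07), Plk1 (-1.62 ± 0.08) and Mki67 (-1.99 ± 0.10). Of 32 matrix and TGF-beta genes 25 fell and 6 rose (the same adjusted over the list alone; mean -1.23; camera adjusted p = 5.07e-09, adjusted p = 0.272 with an estimated correlation): Tgfb2 (-2.92 ± 0.09), the collagen Col1a2 (-3.04 ± 0.13) and the matrix protein Tgfbi (-4.15 ± 0.19) fell. Cytosolic heat shock genes, which encode chaperones, rose in 11 of 14 cases and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 6.81e-05, adjusted p = 0.200 with an estimated correlation), with Hspb8 at 1.34 ± 0.09 and Hsph1 at 1.32 ± 0.10. The cholesterol list fell in 14 of 21 genes and rose in 2 (16 and 2 adjusted over the list alone; mean -0.39; camera adjusted p = 0.000580, adjusted p = 0.337 with an estimated correlation).

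Other called lists were NF-kB and inflammatory genes, where 17 of 28 rose and 3 fell (18 and 5 adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.272 with an estimated correlation), including the cytokine Lif (2.36 ± 0.11). Of 17 astrocyte and progenitor markers 10 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.00276, adjusted p = 0.199 with an estimated correlation), with Hes1 at -1.93 ± 0.09. In the fatty acid list 12 of 19 fell and 2 rose (the same adjusted over the list alone; camera adjusted p = 0.00732, adjusted p = 0.403 with an estimated correlation). Of 22 p53 target genes 15 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.487 with an estimated correlation), the cell cycle inhibitor Cdkn1a by 1.27 ± 0.10. Of 30 oxidative phosphorylation genes 16 fell and 3 rose (16 and 5 adjusted over the list alone; camera adjusted p = 0.0189, adjusted p = 0.508 with an estimated correlation). Of 9 aryl hydrocarbon receptor targets 4 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.0210, adjusted p = 0.272 with an estimated correlation), namely the aldehyde dehydrogenase Aldh3a1 (-2.89 ± 0.11), the oxygenases Cyp2s1 (-1.92 ± 0.12) and Cyp1b1 (-1.63 ± 0.09), and the quinone reductase Nqo1 (-0.51 ± 0.09). None of the 11 lists called in A2/12 was called with an estimated correlation.

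**Figure D2:**
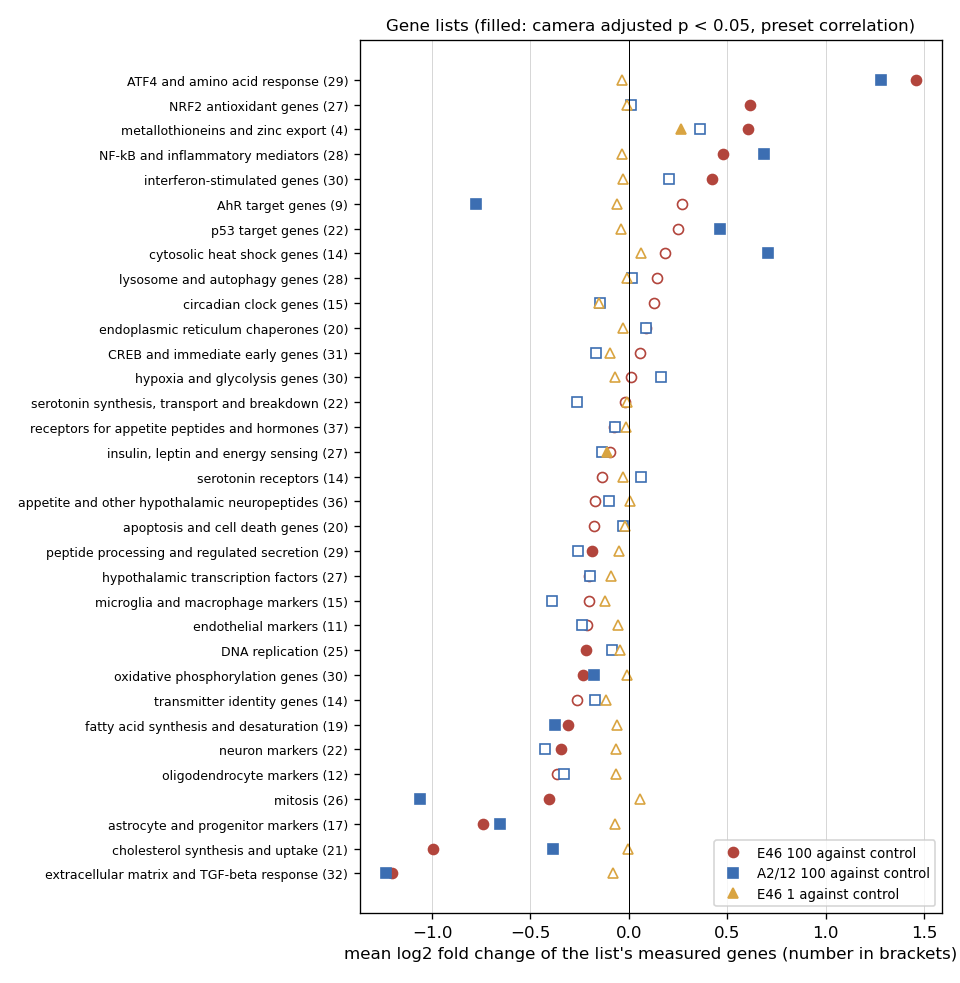
Mean log2 fold change of the measured genes of each of the 33 fixed lists for the 3 comparisons with controls, filled where the camera test with the preset correlation gave an adjusted p below 0.05. The ATF4 list lies at 1.46 in E46 and 1.28 in A2/12 at the labelled 100, and the matrix list at -1.20 and -1.23.

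As in E46, the appetite and serotonin lists were not called as wholes in A2/12. Here too many members were dim, which limits these list tests. In A2/12 controls 18 of 36 neuropeptides, 11 of 37 appetite receptors and 6 of 14 serotonin receptors lay above the receptor gene background. So did 12 of 22 genes of serotonin synthesis, transport and breakdown. Among 36 neuropeptides 3 rose and 4 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.755): Penk fell (-3.93 ± 0.28) and the gut and brain peptide Cck rose (1.16 ± 0.15). Of 37 appetite receptors 2 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.755), among them Npy1r (-2.23 ± 0.10) and the estrogen receptor Esr1 (-1.56 ± 0.12). Of 14 serotonin receptors 2 rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.968), where the mean was 0.06 and the median -0.03. The receptor Htr2a rose from 6.74 ± 0.18 to 8.15 ± 0.17 (1.41 ± 0.11), and the calls of Htr1d (-0.28 ± 0.11) and Htr2b (0.35 ± 0.12) were lost without some single arrays. Of 22 genes of serotonin synthesis, transport and breakdown 2 rose and 7 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.310; mean -0.26, median 0.01). Maob, an enzyme that breaks down amines, fell from 7.75 ± 0.19 to 5.15 ± 0.16 (-2.60 ± 0.11), and Gch1 rose by 1.96 ± 0.16.

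Within positions 5, 7 and 9 the A2/12 counts were 4161, 7057 and 1864, and 8523 with the position number as a block. Replicate 4 of the A2/12 controls had high values of macrophage markers, such as Tyrobp at 6.97 against a mean of 4.11 in the other 3, and without it and E46 control replicate 3 the count was 8368, in an alternative chosen after seeing the data.

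**Figure D3:**
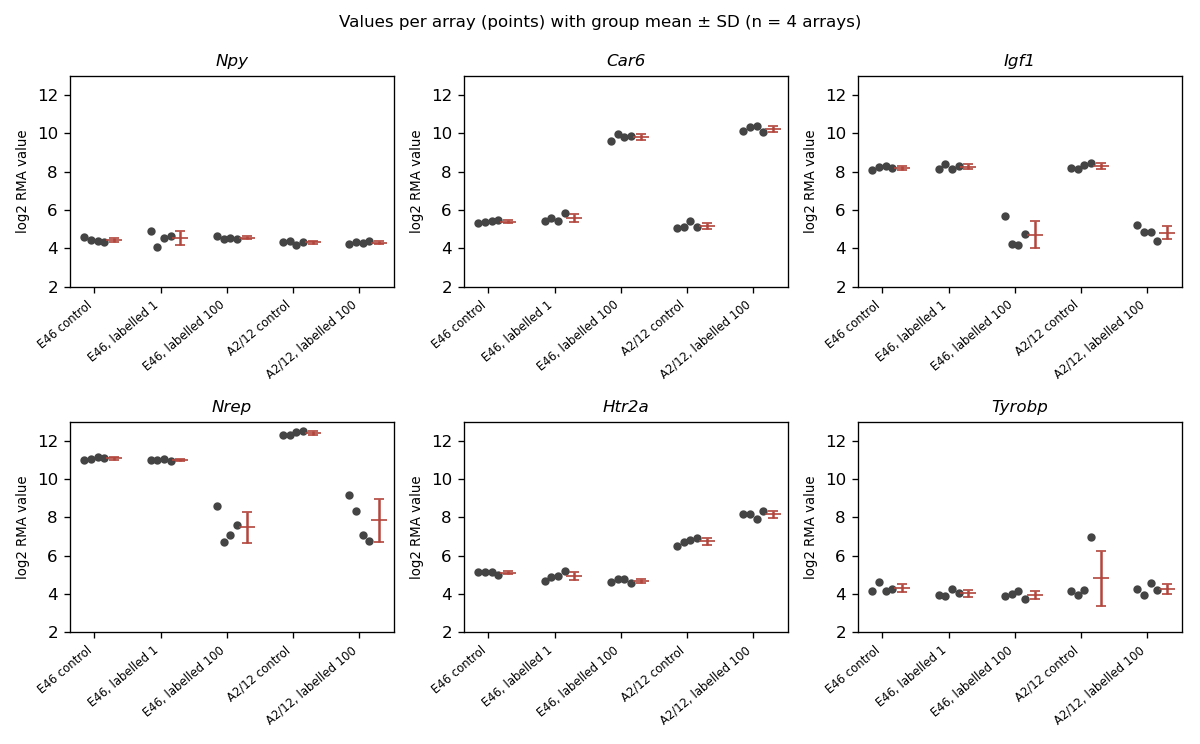
Log2 values of 6 genes in each array (points), with the mean and SD of the 4 arrays of each group beside them. Npy lies between 4.07 and 4.93 in all arrays, Car6 is near 10 in both groups labelled 100, and Tyrobp stands at 6.97 in a single A2/12 control array.

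The fourth question was whether both lines responded alike to serotonin labelled 100. Across genes the responses had a Pearson correlation of 0.690 and a Spearman correlation of 0.641. Of the 5759 genes called in both lines, 3020 rose in both and 2411 fell in both, where 949 and 766 would be expected by chance, and 328 went in opposite directions. The test of the difference itself called 4142 genes, 2089 with a higher change in E46 and 2053 with a higher change in A2/12. The largest differences included Inmt (5.25 ± 0.62) and Agtr2 (5.25 ± 0.34), which were under the background in E46 with and without serotonin, so that a decrease there cannot be seen, and fell in A2/12. They also included Trem3 (-3.68 ± 0.15), H2-M1 (-3.58 ± 0.21) and Dusp9 (-3.42 ± 0.21), which rose in A2/12 and were not called in E46. The difference in the change of Npy was not called (0.12 ± 0.17, adjusted p = 0.704).

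Several of the largest differences were genes that moved in opposite directions. The alcohol dehydrogenase Adh1 rose by 1.05 ± 0.16 in E46 and changed by -3.71 ± 0.16 in A2/12, and Igfbp4, an IGF-binding protein, by 1.16 ± 0.13 and -3.54 ± 0.13. The death receptor Tnfrsf21 changed by 2.14 ± 0.10 and -2.02 ± 0.10. In the other direction, the actin-associated Enc1 changed by -1.13 ± 0.09 in E46 and 2.20 ± 0.09 in A2/12, and the LIM domain gene Lmcd1 by -2.24 ± 0.12 and 0.94 ± 0.12.

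**Figure D4:**
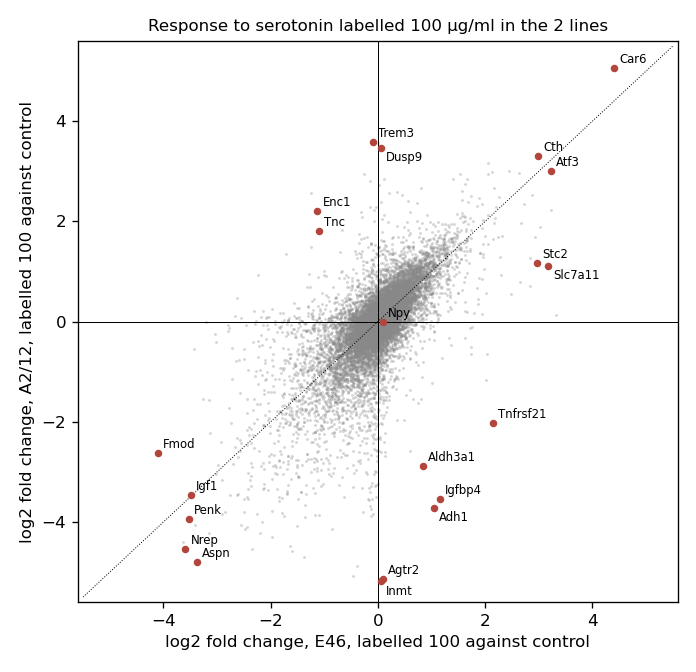
Log2 fold change of each of 18820 genes at serotonin labelled 100 in E46 (horizontal) and A2/12 (vertical), with the dotted line of equal change. The correlation across genes is 0.690, and the named genes include Car6, which rose by over 4 in both lines, and Adh1, Igfbp4 and Tnfrsf21, which rose in E46 and fell in A2/12.

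By lists, 19 of 26 mitosis genes had a higher (less negative) change in E46 than in A2/12 (19 adjusted over the list alone; mean difference 0.66; camera adjusted p = 2.37e-12, adjusted p = 0.227 with an estimated correlation), Ccnb2 by 1.89 ± 0.10. Cholesterol genes had a lower change in E46 in 16 of 21 cases (17 adjusted over the list alone; mean -0.61; camera adjusted p = 2.63e-11, adjusted p = 0.0742 with an estimated correlation), for example Dhcr7 (-1.23 ± 0.10) and Stard4, a sterol transport protein (-1.08 ± 0.11). Of 27 NRF2 genes 15 had a higher and 1 a lower change in E46 (15 and 2 adjusted over the list alone; camera adjusted p = 1.88e-07, adjusted p = 0.0742 with an estimated correlation). Among these were Nqo1 (2.26 ± 0.13) and the detoxifying enzymes Ephx1 (1.86 ± 0.12) and Gstm1 (1.76 ± 0.15). Heat shock genes had a lower change in E46 in 7 of 14 cases (8 adjusted over the list alone; camera adjusted p = 3.19e-05, adjusted p = 0.142 with an estimated correlation), the small chaperone Hspb1 by -2.02 ± 0.17. Of 9 aryl hydrocarbon receptor targets 6 had a higher and 1 a lower change in E46 (the same adjusted over the list alone; camera adjusted p = 0.000176, adjusted p = 0.0742 with an estimated correlation), with Aldh3a1 at 3.72 ± 0.16 and Cyp1b1 at 2.38 ± 0.13. None of these 5 lists was called with an estimated correlation.

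Of 14 serotonin receptors 2 differed in their change (2 adjusted over the list alone; camera adjusted p = 0.397; mean -0.20, median 0.00): Htr2a (-1.84 ± 0.15) and Htr2b (-0.57 ± 0.17). Among 22 genes of serotonin synthesis, transport and breakdown 5 had a higher and 3 a lower change in E46 (the same adjusted over the list alone; camera adjusted p = 0.301), including the monoamine oxidases Maoa (0.79 ± 0.10) and Maob (2.72 ± 0.15). Maob was under the background in E46, so its difference restates the decrease in A2/12. Within positions 5, 7 and 9 the difference called 886, 1593 and 73 genes, and 4060 with the position number as a block. With the doses of the second label, the E46 arrays labelled 1 take the place of those labelled 100 and 7435 genes differ.

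The last comparison asked how the untreated lines differed, as a baseline for both responses. Interferon-stimulated genes were lower and cholesterol synthesis genes higher in E46. Where the lower line lies under the background, as for Sox2, Inmt, Nid1 and Xist here, the difference is a lower bound. Sox2, a transcription factor of neural progenitors, was at 9.72 ± 0.05 in E46 and 4.13 ± 0.16 in A2/12, a difference of 5.59 ± 0.09. The Wnt antagonists Sfrp1 (6.38 ± 0.31) and Sfrp2 (6.36 ± 0.48) were higher in E46. The basement membrane gene Nid1 (-7.64 ± 0.09) and Inmt (-7.70 ± 0.44) were lower in E46. Xist, the RNA of the inactive X chromosome, was at 3.37 ± 0.31 in E46 and 11.73 ± 0.17 in A2/12. Npy was near the receptor gene level in both (0.13 ± 0.12, adjusted p = 0.430).

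Of 18820 genes 7368 differed, 3966 higher and 3402 lower in E46. Other large differences were Adamtsl3 (6.03 ± 0.17), Perp (5.39 ± 0.09), Fndc1 (5.10 ± 0.22) and Ifi202b (5.06 ± 0.13), all higher in E46, and the transcription factor Tfap2b (-6.79 ± 0.11), the lipocalin Apod (-6.62 ± 0.24), the microfibril gene Mfap5 (-6.53 ± 0.13) and the laminin Lama2 (-6.23 ± 0.13), all lower. Interferon-stimulated genes were lower in E46 in 29 of 30 cases and 1 was higher (the same adjusted over the list alone; mean -1.99; camera adjusted p = 1.50e-22, adjusted p = 0.0480 with an estimated correlation), for example Usp18 (-4.87 ± 0.14) and Oasl2 (-4.46 ± 0.14). Cholesterol genes were higher in E46 in 21 of 21 cases (21 adjusted over the list alone; mean 1.01; camera adjusted p = 2.26e-14, adjusted p = 0.0480 with an estimated correlation). Both lists were called with an estimated correlation.

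Of 28 NF-kB and inflammatory genes 18 were lower and 3 higher in E46 (19 and 4 adjusted over the list alone; camera adjusted p = 3.32e-07, adjusted p = 0.108 with an estimated correlation). Examples of the lower genes are the prostaglandin E synthase Ptges (-5.19 ± 0.17) and the adhesion molecule Icam1 (-3.34 ± 0.12). Among 31 CREB and immediate early genes 18 were lower and 5 higher (19 and 5 adjusted over the list alone; camera adjusted p = 0.000271, adjusted p = 0.514 with an estimated correlation), with Rgs2, a regulator of G protein signalling, at -3.82 ± 0.14. The matrix list had 16 lower and 8 higher of 32 (the same adjusted over the list alone; camera adjusted p = 0.00777, adjusted p = 0.746 with an estimated correlation) and the ATF4 list 18 higher and 4 lower of 29 (19 and 4 adjusted over the list alone; camera adjusted p = 0.00844, adjusted p = 0.746 with an estimated correlation), where the lipoprotein receptor Vldlr differed most (4.53 ± 0.08). Of 30 oxidative phosphorylation genes 12 were higher (13 adjusted over the list alone; camera adjusted p = 0.0205, adjusted p = 0.717 with an estimated correlation). Of 17 astrocyte and progenitor markers 8 were higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.0427, adjusted p = 0.332 with an estimated correlation). These 6 lists were not called with an estimated correlation.

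Among 27 hypothalamic transcription factors 8 were higher and 4 lower in E46 (the same adjusted over the list alone; camera adjusted p = 0.183), including the forebrain factors Lhx2 (4.33 ± 0.13), Six3 (3.75 ± 0.12) and Nkx2-1 (2.33 ± 0.10). Of 22 neuron markers 7 were higher and 6 lower (8 and 6 adjusted over the list alone; camera adjusted p = 0.972; mean -0.12, median 0.07), with the growth cone protein Stmn2 at 5.09 ± 0.09 in E46 and 9.14 ± 0.06 in A2/12. In the appetite receptor list 5 were higher and 3 lower of 37 (the same adjusted over the list alone; camera adjusted p = 0.835), Npy1r among the lower (-1.32 ± 0.10).

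As levels, 6 of 14 serotonin receptors lay above the receptor gene background in the controls of each line. Htr2a was at 5.11 ± 0.10 in E46 and 6.74 ± 0.18 in A2/12, and Htr1b at 4.49 ± 0.10 and 5.43 ± 0.28. In the tested list 2 were higher and 2 lower in E46 (the same adjusted over the list alone; camera adjusted p = 0.929; mean -0.07, median 0.05): Htr2b (0.56 ± 0.12) and Htr1d (0.32 ± 0.11, lost without some single arrays) higher, Htr2a (-1.63 ± 0.11) and Htr1b (-0.94 ± 0.11) lower. The serotonin transporter Slc6a4 was at 3.81 ± 0.10 in E46 and 3.73 ± 0.06 in A2/12, and the synthesis enzymes Tph1 and Ddc at 3.55 ± 0.09 and 3.43 ± 0.10 in E46, all under the background. Among 22 genes of serotonin synthesis, transport and breakdown 4 were higher and 6 lower in E46 (the same adjusted over the list alone; camera adjusted p = 0.459; mean -0.38, median 0.11). Maoa was at 9.60 ± 0.14 in E46 and 10.04 ± 0.08 in A2/12, and Maob at 3.61 ± 0.13 and 7.75 ± 0.19 (-4.14 ± 0.11).

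Within positions 5, 7 and 9 the baseline comparison called 3782, 3674 and 1292 genes, and 7284 with the position number as a block. Without E46 control replicate 3 and A2/12 control replicate 4, an alternative chosen after seeing the data, it called 6360, and the astrocyte and oxidative phosphorylation lists were no longer called.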

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

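The tests of leaving out the 4 arrays of low upper quartile, macrophage-like cells, another sample, drift along positions, an array of the other line, a hidden change as wide as that at the labelled 100, exchanged dose labels and exchanged residuals below were chosen after the result was seen. The other tests were planned.

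Replicate 4 of the A2/12 controls had high values of macrophage markers: of 15 fixed microglia and macrophage markers, 10 lay above all 3 other A2/12 controls, 4 of them by over 2 log2 units, with Fcer1g at 8.03 against 4.70, Tyrobp at 6.97 against 4.11, Spi1 at 6.53 against 3.98 and Csf1r at 6.50 against 4.01. The 50 genes most specific to A2/12 against E46 differed from the other 3 controls by a median of 0.0429. This argues against an E46 sample under this label. These genes were chosen with this array among the A2/12 controls, and they cannot tell another A2/12 sample apart. The range of the array is argued against too, since 92.3% of the median excess of the markers was left after quantile normalization. RNA of macrophage-like cells in that sample is a candidate explanation. It stays open, because C1qa (4.49 against 4.41) and C1qc (3.79 against 3.60) were not above all others. Tmem119 was equally high in the other controls (10.06 against 10.09), so it does not speak for or against this explanation. Where such RNA would have come from was not tested, since the labels do not say.

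In A2/12, a line described as unresponsive, 8645 genes changed. For 2-fold changes, a drift from row to row of the array positions is argued against. Of 2028 genes called with a 2-fold change in the arrays outside position row F, 99.1% had the same sign and at least 50% of the size within that row. Smaller changes, which are most of the 8645, were not checked in this way. In row F control replicate 4 lies at 5 and serotonin replicates 1 and 2 at 7 and 9, so a drift within the row stays open. An array of the other line is argued against by the Y-linked genes, whose highest mean in an A2/12 serotonin array lay 0.186 above the A2/12 controls, where E46 arrays lie at 7.29 to 8.10 and A2/12 arrays at 3.38 to 3.65. The range of the arrays is argued against by 8902 called genes after quantile normalization. A response of the cells to serotonin at this dose may remain as a hypothesis, which the single dose in this line cannot test further.

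In E46 at the labelled 1, 2 genes were called (284 without replicate 2 at that dose). Without the 4 arrays of low upper quartile 1 gene was called, neither of these 2, but this leaves 2 arrays against 3, where 44.8% of simulated 1.5-fold and 1.49% of 1.2-fold changes were recovered, so whether such arrays hide a small change stays open. A hidden change as wide and as large as that at the labelled 100 is argued against, since 2 arrays of that dose against the same 3 controls gave 6206 to 7072 calls. A change as wide but smaller in size could be missed in this way and stays open. Exchanged dose labels stay open: the response of the arrays labelled 1 had a correlation of 0.0477 with the A2/12 response at 100, against 0.690 for the arrays labelled 100, but both lines need not respond alike. A weaker form of the response at 100 stays open too: 67.9% of 1208 genes leaned the same way with the controls divided (66.7 to 69.7% over 6 ways), while the median change at the labelled 1 was -0.03 for genes that had risen and -0.13 for genes that had fallen. This share is not evidence for it by itself. Of the 1208 genes 773 had fallen and 435 had risen, and the median change of all genes at the labelled 1 was -0.04. A general downward lean alone could thus make most of them lean the same way.

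Other splits of the same arrays tell how often as many calls arise when the arrays are regrouped. Only the real split, 1 of 35, gave as many for E46 at the labelled 100 (7451 genes, highest other split 1). The same held for the labelled 100 against the labelled 1 (7796, highest other 2) and for A2/12 (8645, highest other 0, by limma). It held for the untreated lines as well (7368, highest other 2). Every other split mixes the 2 groups compared, so the changes themselves enter the spread within its groups and lower its calls. Few calls in those splits therefore do not measure how many arise by chance. A share of 1 of 35 is the smallest that these splits can give. They cannot exclude a chance difference between cultures, since no label says which arrays came from separate cultures. A chance regrouping of arrays is not excluded for E46 at the labelled 1, where 3 of 35 splits gave as many calls (real 2, highest other 126). The split with 126 calls differs from the real one only in that E46 control replicate 1 and replicate 2 at the labelled 1 change sides. Without that replicate 2 the real split gave 284 calls. The split with 126 also puts all 3 low upper quartile arrays of this comparison on one side. The other 4 splits that do so gave 0, 0, 1 and 27 calls by limma. What sets these arrays apart was not tested. For the difference of the responses 6 of 100 draws gave as many calls as the real 4142, the highest 7963, but draws that mix the treatment labels in one line more than in the other take in a response. With line and treatment effects removed and residuals exchanged, 1 of 100 draws gave as many (real 4365, highest other 1870).

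The change at the labelled 100 differed between the lines in 4142 genes by the test of the difference, and 328 of these passed in opposite directions (142 up and 186 down in E46). By camera 5 gene lists differed with the preset correlation and 0 with the estimated one. Of 14338 probe sets with no gene name or several, which the comparisons do not use, 1886 changed in E46 and 2643 in A2/12 at the labelled 100.

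Single arrays stood apart from the other 3 of their group in 11 of 175 list and array summaries and in 35 of 656 gene and group pairs, where about 1 in 20 (32.8 of the pairs) is expected by chance. The values below are the gap to the nearest array as a share of the range of the group. In E46 control replicate 1 they were 0.838 for the median (5.33 against 5.54) and 0.911 for the upper quartile (8.09 against 8.25) of all probe sets, and 0.941 for the ATF4, 0.910 for the heat shock and 0.857 for the circadian list means. The same array stood apart in Cth (0.838), Npy1r (0.968), Dusp9 (0.872), Cyp1b1 (0.898), Adamtsl3 (0.911), Kif5c (0.943), Arnt2 (0.856), Htr1a (0.912) and Tph1 (0.836). Other E46 controls stood apart in the endothelial list (0.978) and Nkx2-1 (0.873), both replicate 2, and in Htr2a (0.961) and Fads2 (0.850), both replicate 4.

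At the labelled 100 in E46, replicate 1 stood apart in Islr (0.865; 5.95 against 4.91), Cdt1 (0.929), Thbs1 (0.859), Acta2 (0.952), Slc1a3 (0.934), Mgll (0.932) and Tnc (0.859), replicate 2 in the aryl hydrocarbon receptor list (0.832) and Igfbp4 (0.894), and replicate 3 in Gclm (0.891) and Ccnb2 (0.934). At the labelled 1, replicate 3 stood apart in Ppp1r15a (0.837). In A2/12 controls, replicate 1 stood apart in Ndufa4 (0.861), Sulf1 (0.921) and Slc7a5 (0.921), replicate 2 in the NRF2 (0.8292) and circadian (0.898) lists, Sesn1 (0.851), Tgfb2 (0.937), Nr4a2 (0.866) and Pts (0.964), replicate 3 in Car6 (0.855) and Nid1 (0.833), and replicate 4 in Arhgdib (0.914; 9.07 against 7.66) and Serping1 (0.914). In A2/12 at the labelled 100, replicate 1 stood apart in the circadian list (0.850), replicate 2 in the oligodendrocyte list (0.847) and replicate 4 in H2-M1 (0.946; 7.34 against 6.77).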

How the results depend on the processing

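Alternatives that left out the 4 arrays of low upper quartile, used the upper quartile as a covariate, or left out 2 control arrays, E46 replicate 3 and A2/12 replicate 4, with high values of some intestinal or macrophage genes, were chosen after seeing the data. The other alternatives were planned. Where a position number leaves 1 array in a group, that array is assumed to vary like the other groups, and signal over background limits what can be said of dim genes. The position number does not account for the position row, which follows the order of the groups. Unless a reason is given, the cause of a change was not tested.

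For E46 at the labelled 100 (7451 genes, 14 lists) the positions 5, 7 and 9 alone, with fewer arrays, called 3183, 3469 and 871 genes, and position 9 called 9 lists. A fold of at least 1.5 left 3115, and the dose of the description gave 2 genes and 2 lists, since it exchanges the groups. For the labelled 100 against 1 the values were 2051, 5107 and 1371, and 3220 with the fold, and the description turned the direction of the 7796 genes (3346 up, 4450 down). A2/12 gave 4161 at position 5, 1864 at position 9 and 4397 with the fold. The difference of responses gave 886, 1593 and 73, 2293 with the fold, and 7435 genes and 11 lists with the dose of the description. The untreated lines gave 3782, 3674 and 1292, and 2983 with the fold. With camera and an estimated correlation the called lists numbered 3, 1, 3, 0, 0 and 2 in the order of the comparisons above in the methods.

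For E46 at the labelled 1 (2 genes, 2 lists) limma called 0 genes with the line fitted alone (2746 at an unadjusted p below 0.05), 0 with the fold, 0 at positions 5 and 7 (453 and 3656 unadjusted) and 1 at position 9. It called 1 with the position as a block, quantile normalization, median centring, the dimmer genes left out, probe sets uncollapsed, the 4 arrays left out or the 2 arrays left out. The gene called without the 4 arrays was neither of the 2. Snord22 lost its call with the line fitted alone, at each position number, with the fold and without the 4 arrays. The dose of the description gave 7451 genes and 14 lists. Lists called were 1 at position 7, 0 at position 9 and 4 with median centring.

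Replicate numbers do not pair the arrays throughout: 8 of 20 same-numbered pairs had correlated deviations over 0.1 (-0.262 to 0.406), and 6 matched best with their own number. Replicate 1 did so between all E46 groups (0.237, 0.372 and 0.406), so a pairing of these arrays stays open. With the replicate block the genes called were 7622, 1, 8095, 8833, 4364 and 5594, with 1 list for E46 at the labelled 1 and 4 for the untreated lines.

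Leaving out each array in turn gave 6773 to 7272 genes and 11 to 14 lists for E46 at the labelled 100, 1 to 284 and 1 to 3 at the labelled 1, 7037 to 8194 and 10 to 11 between the doses, 8190 to 8439 and 11 to 13 in A2/12, 3751 to 4257 and 5 to 8 for the difference, and 6810 to 7183 and 8 to 9 for the untreated lines. The 284 arose without E46 replicate 2 at the labelled 1, 4 genes without its replicate 4, 1 list without E46 control replicate 4, and the 8 lists without E46 control replicate 1. The correlation of the doses ranged from 0.153 to 0.227, and was 0.120 with the controls divided.

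Npy passed in 0 settings by limma, but its small change turned sign in some. Its level was near or under the background, for example 4.31 against 4.36 in A2/12 controls and 4.54 against 4.66 in E46 at the labelled 1. These values therefore cannot tell whether serotonin left Npy unchanged. At the labelled 1 it was -0.40 at position 5, -0.043 without the 4 arrays, and ranged from -0.035 (without E46 replicate 1 at that dose) to 0.25 (without replicate 2) with single arrays left out. For the labelled 100 against 1 it was -0.28 at position 9, -0.025 with median centring, -0.030 without replicate 1 at 100, and with single arrays left out from -0.15 (without replicate 2 at 1) to 0.13 (without replicate 1 at 1). In A2/12 it was 0.045 with array weights, 0.14 at position 9, from -0.055 (without control replicate 3) to 0.0070 (without serotonin replicate 1) with single arrays left out, 0.0046 without control replicate 2 or the 4 arrays, and 0.11 with the covariate. The difference of responses was -0.034 at position 9. Sult1a1, lower in untreated E46, was 0.0069 at position 7.

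For the lists, 535 of 630 values kept direction and side of the threshold and 95 lost the call, 36 of these with the estimated correlation. For the named genes 4828 of 5020 did, 189 lost the call, 2 gained it and 1 turned. Without the 2 control arrays the DNA replication list in E46, the astrocyte and oxidative phosphorylation lists of the untreated lines, Boc and Htr1d lost the call.

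Single arrays left out ended these calls. Boc lost it without each E46 control and without replicates 1 and 3 at the labelled 1, where Olfr959, Stx19 and Pmel gained it without replicate 2. Htr5b in E46 lost it without control replicate 2 or serotonin replicate 4. In A2/12, Htr1d lost it without control replicates 3 or 4 or any serotonin array, and Htr2b without control replicates 1 or 3 or serotonin replicate 3. Between untreated lines, Htr1d lost it without E46 replicates 3 or 4 or A2/12 replicates 1 or 2. In E46 at the labelled 100, the DNA replication list lost it without control replicates 3 or 4 or serotonin replicates 1 or 3, peptide processing without control replicates 1 or 2 or serotonin replicates 1 or 3, and metallothioneins without serotonin replicate 1. At the labelled 1 the energy sensing list lost it without control replicate 4 or replicates 1 or 3, and between untreated lines the astrocyte list without E46 replicate 1 or A2/12 replicate 4.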

Other observations

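Genes of the circadian clock, of glycolysis and of energy sensing, which were fixed as lists, also moved at the labelled 100, without their lists being called by camera. Of 15 clock genes 6 rose and 6 fell in E46 (7 and 6 adjusted over the list alone; mean 0.13, median -0.07; camera adjusted p = 0.739), and 6 rose and 6 fell in A2/12 (6 and 7 adjusted over the list alone; camera adjusted p = 0.696). The clock repressor gene Ciart rose by 2.06 ± 0.11 in E46 and 2.13 ± 0.11 in A2/12, while Per3 changed by -0.82 ± 0.10 and -2.05 ± 0.10. Of 30 hypoxia and glycolysis genes 8 rose and 11 fell in E46 (the same adjusted over the list alone; mean 0.01, median -0.15; camera adjusted p = 0.520): hexokinase Hk2 rose by 2.05 ± 0.12 and the growth factor Vegfa by 1.38 ± 0.10. In A2/12 they rose by 1.55 ± 0.12 and 1.59 ± 0.10. Of 27 insulin, leptin and energy sensing genes 10 rose and 13 fell in E46 (the same adjusted over the list alone; camera adjusted p = 0.572). The insulin receptor substrate Irs1 fell (-1.54 ± 0.11), and Cpt1a, which admits fatty acids to mitochondria, changed by -1.48 ± 0.12 in E46 and -3.11 ± 0.12 in A2/12.

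The following genes, apart from the 20 further intestinal genes below, were chosen after their values were seen. In A2/12 control replicate 4, Ccl3 was at 11.09, but it also reached 7.84 in A2/12 serotonin replicate 3, 7.52 in E46 control replicate 2 and in E46 replicate 4 at the labelled 1, and 6.08 and 6.68 in A2/12 control replicates 2 and 3. In the same array Lyz2 was at 9.02, Clec4e at 8.07 and Wfdc17 at 7.81, where the highest of the 19 other arrays were at 5.40, 4.66 and 4.64. In E46 control replicate 3 the intestinal gene Reg3g was at 7.01 and Zg16 at 5.92. A further 20 intestinal genes were listed before their values were looked up. Of these, 16 were above the other E46 controls in that array, 1 of them by over 1 log2 unit (Sis, 4.44 against 3.32). The median excess was 0.29, and Fabp1, Apoa4, Phgr1 and Spink4 were not above all 3 others. Between the serotonin arrays at the labelled 100, Inmt lay between 5.13 and 8.33 in A2/12 and Igf1 between 4.15 and 5.70 in E46.

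The number of genes over 1 log2 unit above the other 3 arrays of the group was 133 in A2/12 control replicate 2 (9 over 2 log2 units), 72 in A2/12 control replicate 4 (34), 30 in E46 replicate 1 at the labelled 1 (0) and 6 in E46 control replicate 3 (4). In each of the other arrays it was at most 7.

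The mean of 3 Y-linked genes was 7.29 to 8.10 in E46 arrays, with Xist at 2.94 to 3.91, and 3.38 to 3.65 in A2/12 arrays, with Xist at 11.27 to 11.94.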
